A study of Mus musculus with 6 samples.

How the data were processed

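RNA was measured by sequencing in 6 tumours grown under the skin of athymic nude mice from STS26T cells, a human malignant peripheral nerve sheath tumour line. In 3 tumours the mice had received antibodies against endoglin (ENG), a co-receptor for ligands of the TGF-beta family, and in 3 they had received an IgG control. Per the labels' protocols, the anti-ENG treatment combined TRC105, which binds the human protein, with M1043, which binds the mouse protein. Both arms were dosed at 10 mg/kg, 2 times a week into the peritoneum, for 3 weeks. Groups and replicate numbers were taken from the sample titles.

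The deposited table holds FPKM values (fragments per kilobase of transcript and per fixed number of mapped fragments) for 23284 gene symbols in 6 columns, 1 per tumour. Per the labels' protocols, polyadenylated RNA was sequenced. These protocols name a pair of library kits and a pair of Illumina instruments without saying which was used for which sample. Strand use in the counting is therefore not given in the sources used here. If kit or instrument differed between the groups, that difference cannot be told apart from treatment. Per the submitters' processing notes, the tools were FastQC 0.10.1, TopHat2 2.0.10, Bowtie 1.0.0, SAMtools 0.1.1.9, Cufflinks 2.2.1 and Cuffnorm, with the human build GRCh37 (hg19). The scaling that Cuffnorm applied is not given in the sources used here. The labels give mouse as the organism, while the gene symbols are human, so RNA of the mouse host can enter these values only where its reads align to the human genome. How mouse reads were treated is not given in the sources used here.

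FPKM values are not counts, and no count test was run. The total depth is unknown. The value of 1 fragment in genes of up to 0.05 FPKM gave relative depths, taken against IgG control 1, of 1.18 and 1.09 for IgG control 2 and 3 and of 1.46, 1.23 and 1.14 for anti-ENG 1, 2 and 3. The deposited FPKM values summed to between 410786 and 475146 per sample. The 50 most abundant genes took 16.9 to 19.9% of that sum. No pair of samples shared identical values above 0.

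The groups were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend and no covariate, in the 12586 genes with a mean of at least 1 FPKM over all 6 samples. Fold changes are on this log2(FPKM + 1) scale, which understates changes of low genes. P-values are two-sided and adjusted by Benjamini-Hochberg, with a threshold of 0.05. With 3 samples against 3, an exact permutation test cannot give a two-sided p under 0.1. The tumours' description codes share a number within the IgG control 2 and 3 pair and within the anti-ENG 1 and 2 pair. Within each pair 1 code ends in L and the other in R. The labels do not say whether such tumours came from 1 animal. P-values then measure only the spread between these samples.

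Gene lists were tested with camera from limma at its preset correlation of 0.01, over the 29 of 34 lists with at least 3 tested members. Camera with an estimated correlation and fry were run beside it. The 34 lists, the tests, the alternatives listed in advance and the rule for naming genes were fixed before the data were examined. That rule took the 12 genes of smallest unadjusted p in each direction, because none passed the threshold. It also took up to 4 members of smallest p in each list, and ENG. Unnamed loci, pseudogenes and small RNAs were passed over. Some genes that the rule picks are not reported here. Of 587 genes on the lists, 14 were absent from the table under any symbol tried: the 13 mitochondrially encoded genes and TIGAR.

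The limma step was tested on simulated data made from the same 12586 genes, with 3 samples against 3. It recovered 7.2% of planted changes of 0.5 on the log2 scale, 68% of those of 1, 96.8% of those of 2 and 99.6% of those of 3, with 40 false calls in 5 runs. Each run held 200 planted changes at once, and the Benjamini-Hochberg adjustment is milder when many genes change. In the data no gene passed, so these recovery rates need not hold for a gene that changes alone or among few. A planted shift of 0.5 in 1 list was called in 5 of 5 runs, with 4 other lists called over all runs. The simulated genes were drawn independently of each other. In the data the estimated correlation was 0.050 within the S phase list, 0.475 within the oxidative phosphorylation list and 0.90 within the NF-kappaB list. The rate of other lists called in the simulation therefore need not hold here.

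Alternatives covered the pseudocount, the filter on low values, scaling, the variance model, sample weights, blocks by replicate or code number, the set test and leaving out each tumour. Cyclic loess normalization, leaving out both tumours at the ends of the first principal component and a correction for length and GC content were added after seeing the data. That correction used the transcript of the mouse orthologue by symbol (GENCODE M21), since a human annotation was not used here, and covered 78.8% of tested genes, with 95.5% of the oxidative phosphorylation and 100% of the ribosomal list. Scripts ran in Python 3.11.15 and R.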

Results

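The expression table covered 6 STS26T xenograft tumours, 3 from mice given anti-ENG antibodies and 3 from mice given IgG. Of 23284 genes listed, 18915 were above 0 in at least 1 tumour and 12586 entered the tests. Each tumour had between 12358 and 12624 genes at 1 FPKM or more. Correlations of log2(FPKM + 1) between tumours, across genes, ran from 0.959 to 0.983 within groups and from 0.932 to 0.984 between groups. The lowest was that between IgG control 1 and anti-ENG 1. Those tumours lay at opposite ends of the first principal component, which held 44.6% of the variance.

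The comparison asks what blocking endoglin on tumour and host cells does to the RNA of these tumours. At the preset correlation of camera, lists of oxidative phosphorylation, ribosomal protein and cell division genes were called higher in the anti-ENG tumours than in the IgG tumours, each lost at an adjusted p of 0.458 or more with an estimated correlation. Lists of collagen, fibroblast, TGF-beta, invasion, histone and NF-kappaB genes were called lower, each lost at an adjusted p of 0.783 or more with an estimated correlation. The NF-kappaB median turned to 0.066 without IgG control 1, and the ribosomal call ended with quantile normalization (camera adjusted p = 0.0621). The shifts were modest, with medians of the called lists between a 1.71-fold lower and a 1.28-fold higher level. No single gene passed the adjusted threshold.

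ENG itself, the target of the antibodies, had 41.0, 23.9 and 22.1 FPKM in IgG control 1, 2 and 3 and 15.5, 29.5 and 26.7 FPKM in anti-ENG 1, 2 and 3. The means were 29 ± 10.4 FPKM (SD, n = 3) in the IgG group and 23.9 ± 7.39 (SD, n = 3) in the anti-ENG group. The log2 fold change of ENG was -0.26 (SE 0.30, limma adjusted p = 0.751), and the exact two-sided permutation p was 0.6, where 0.1 is the smallest possible. The difference thus lay within the spread between tumours. Without IgG control 1 the log2 fold change of ENG was 0.0048, and without anti-ENG 1 it was 0.007. These values are of the human gene. The RNA of mouse endoglin, the target of M1043, was not measured separately.

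By limma, 0 genes were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.529. At an unadjusted p under 0.05 there were 1154 genes, 9.17% of those tested, where 629 would be expected by chance. Of these, 700 were higher and 454 lower in the anti-ENG tumours. This split was 496 higher and 572 lower with upper quartile rescaling, 453 and 498 after cyclic loess normalization, and 170 and 1083 with each sample rescaled to the same sum of FPKM. The last of these moved the median log2 fold change of all genes to -0.108, so single-gene directions are relative to the scaling used. The values of the groups did not overlap in 2183 genes, 17.3% of those tested, against 10% by chance.

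Among the 12 genes of smallest p with higher estimates was ATP5G1, a gene for the membrane ring subunit of the mitochondrial ATP synthase. Its mean was 47.4 ± 4.73 FPKM (SD, n = 3) under IgG and 80.1 ± 4.36 (SD, n = 3) under anti-ENG, a log2 fold change of 0.75 (SE 0.12, limma adjusted p = 0.529). PCNA, the sliding clamp of DNA replication, had means of 96.2 and 149 FPKM. PCNA-AS1, an antisense transcript of that locus, had means of 91.5 and 156 FPKM, and reads of the pair may not be separable where strand was not used. KPNA2, a nuclear import receptor, had 80.2 and 112 FPKM. The complement gene C7 had the largest log2 fold change of the 12, 1.9, from 2.12 ± 1.5 to 9.69 ± 1.89 FPKM (SD, n = 3 each). The others were DPH5 of diphthamide synthesis at 0.59, PTRHD1 at 0.76, C5orf46 at 0.83, PIGU of GPI anchor attachment at 0.57, FLYWCH2 at 0.57, SPA17 at 0.56 and LSMD1 at 0.52. None passed the threshold, with an adjusted p of 0.529 for each.

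Among the 12 genes of smallest p with lower estimates was FIBIN, with 7.10 ± 0.361 FPKM under IgG and 2.43 ± 0.737 under anti-ENG (SD, n = 3 each), a log2 fold change of -1.26. MAN1A1, a Golgi mannosidase that trims N-glycans, had 16.8 ± 2.89 and 7.53 ± 0.959 FPKM (SD, n = 3 each), a log2 fold change of -1.06. AHRR, the repressor of the aryl hydrocarbon receptor, had a log2 fold change of -1.66, and the calcineurin-dependent transcription factor NFATC4 had -1.45. The mitochondrial carrier SLC25A27 had a log2 fold change of -0.84, the forkhead factor FOXF1 -0.85, RFX8 -0.86 and PLXDC1 -0.99. The pro-apoptotic gene BMF had -0.69, the GABA receptor subunit gene GABBR1 -0.66, KIAA0895L -0.60 and AHSA2 -0.55. Each had a limma adjusted p of 0.529. In all 24 genes the 3 tumours of one group lay apart from the 3 of the other, and leaving out 1 tumour moved 0 of the 24 log2 fold changes by over 1.5 times. Picking genes by smallest p in these same tumours favours both outcomes, so neither is a separate check.

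**Figure D1:**
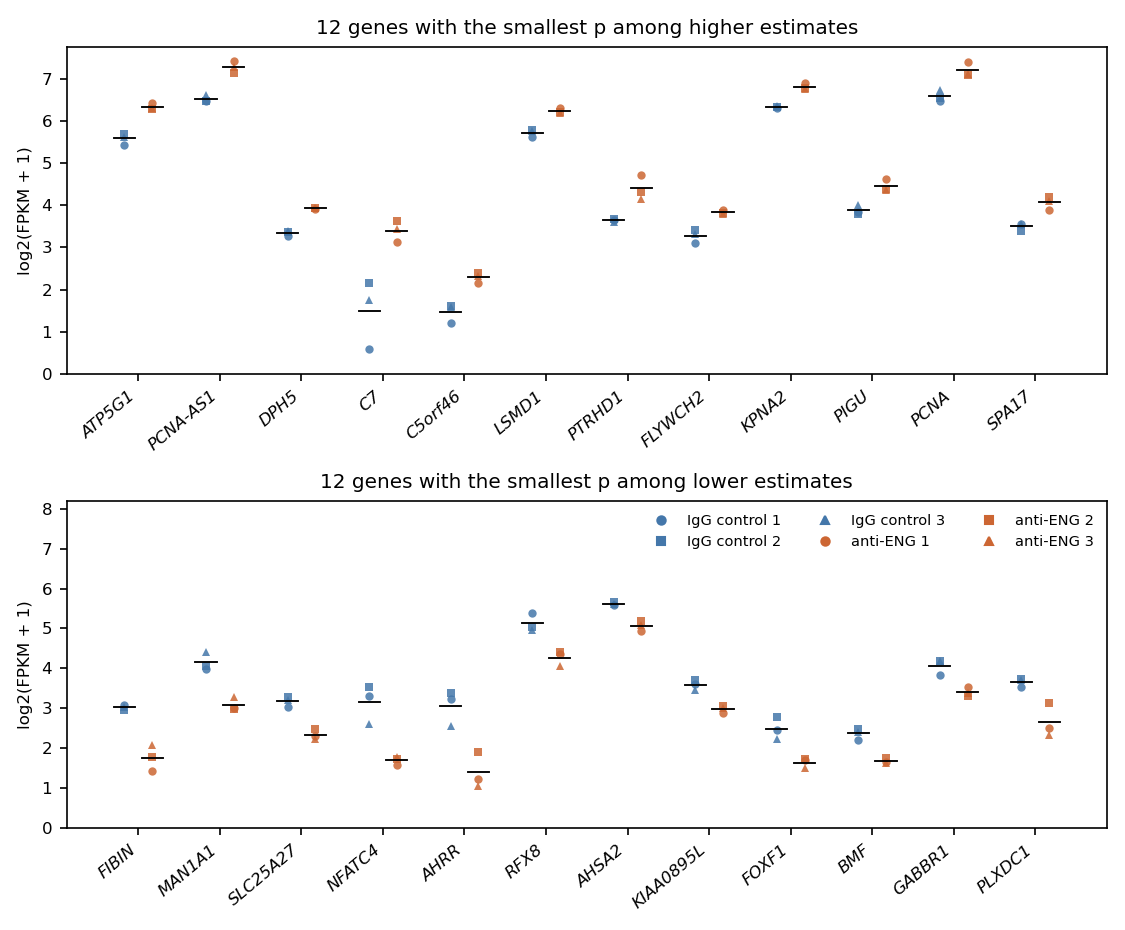
Log2(FPKM + 1) of the 12 genes of smallest p with higher and the 12 with lower estimates under anti-ENG, 1 point per tumour, with horizontal lines at the group means (n = 3). The tumours of the groups lie apart in all 24 genes, which the choice by smallest p favours, and C7 has a log2 fold change of 1.9 and AHRR one of -1.66.

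Nuclear genes of oxidative phosphorylation were higher in the anti-ENG tumours in 22 of 22 members, and the groups lay apart in 18. The median member was 1.25-fold higher (median log2 fold change 0.32, camera adjusted p = 9.0e-11), with an adjusted p = 0.783 with an estimated correlation. Of these members 19 lay in the top 10% of genes by expression, where the median of all genes was 0.16. The list median was 0.16 after cyclic loess normalization (camera adjusted p = 2.19e-05) and 0.19 without both IgG control 1 and anti-ENG 1 (1.35e-06). Members included the complex I gene NDUFS5, with 187 ± 3.28 and 248 ± 27.8 FPKM (SD, n = 3 each). NDUFA4 had a log2 fold change of 0.46 and the complex III gene UQCRB 0.45. ATP5G1 was the 1 member that passed when adjusted over the list alone, against 0 adjusted over all genes tested.

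Cytosolic ribosomal protein genes were higher in 25 of 25 members, with the groups apart in 10 and a median log2 fold change of 0.34 (camera adjusted p = 1.2e-08). That call was lost with an adjusted p = 0.783 with an estimated correlation. RPS6 had 1060 ± 84.0 and 1505 ± 311 FPKM (SD, n = 3 each), and RPL32 had 231 ± 25.9 and 328 ± 62.0 (SD, n = 3 each). RPL30 and RPL7 had log2 fold changes of 0.47 and 0.57. No member passed when adjusted over the list alone (0 genes). All 25 members lay in the top 10% of genes by expression, where the median log2 fold change of all genes was 0.16, against -0.076 in the lowest 10%. The camera adjusted p was 0.0621 with quantile normalization and 0.0925 after cyclic loess normalization, so both ended this call. Without anti-ENG 1 the median was 0.21 and the list was still called (1.2e-06).

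Genes of DNA replication and of mitosis were higher in all members tested. Of the S phase and replication list, 20 of 20 were higher, 6 of them with groups apart (median log2 fold change 0.26, camera adjusted p = 1.5e-06). Of the G2/M list, 20 of 20 were higher, 11 with groups apart (median 0.36, camera adjusted p = 9.2e-08). The calls were lost at an adjusted p = 0.458 with an estimated correlation for S phase and an adjusted p = 0.783 with an estimated correlation for G2/M. CCNE2, a cyclin of S phase entry, had a log2 fold change of 0.48, the polymerase gene POLA1 0.42 and the helicase gene MCM4 0.32. CCNB1, the mitotic cyclin, had 45.0 ± 3.05 and 68.7 ± 14.3 FPKM (SD, n = 3 each), and the mitotic kinase gene AURKA had 38.8 ± 1.82 and 53 ± 5.94 (SD, n = 3 each). Without anti-ENG 1 the G2/M median was 0.23, still called (camera adjusted p = 1.48e-06). CDC20 and TPX2 had log2 fold changes of 0.39 and 0.45. Adjusted over the list alone, 1 S phase gene passed, PCNA, and 0 G2/M genes. Replication-dependent histone genes were lower in 10 of 11 members, with the groups apart in 2 (median -0.32, camera adjusted p = 0.0329, and adjusted p = 0.822 with an estimated correlation). Polyadenylated RNA was sequenced, so any histone transcripts without a poly(A) tail would be missed, and these values cannot be set against the S phase genes. HIST4H4 had 1.47 and 0.551 FPKM, a log2 fold change of -0.68, and HIST2H2AC had 2.23 and 1.48 FPKM, one of -0.38. Of the histone genes 0 lay in the top 10% by expression, and 0 passed when adjusted over the list alone. Without anti-ENG 1 the histone median turned to 0.074 (camera adjusted p = 0.973), and without IgG control 2 it was -0.11 (0.198). The histone call also ended at larger or similar medians, -0.39 without IgG control 1 (0.0538), -0.37 at a minimum of 5 FPKM (0.171), and -0.35, -0.28 and -0.31 with upper quartile (0.0641), quantile (0.0748) and cyclic loess (0.099) normalization.

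Collagen and basement membrane genes were lower in 21 of 22 members, with the groups apart in 5 and a median log2 fold change of -0.45 (camera adjusted p = 1.2e-06). That call was lost with an adjusted p = 0.783 with an estimated correlation. COL6A1 had 677 ± 170 and 412 ± 126 FPKM (SD, n = 3 each), COL6A2 had a log2 fold change of -0.77, and NID1, the basement membrane linker nidogen, had -0.85. The 3 tumours of one group lay apart from the 3 of the other for these 3 genes and for COL5A1 at -0.40. Fibroblast markers were lower in 10 of 13 members, with the groups apart in 0, against 17.3% of all genes tested. Their median log2 fold change was -0.77 (camera adjusted p = 0.00353, and adjusted p = 0.783 with an estimated correlation). DCN, the proteoglycan decorin, had 27.9 ± 18.4 and 9.12 ± 5.23 FPKM (SD, n = 3 each). LUM and SFRP2 had log2 fold changes of -1.35 and -1.30, and COL3A1 had -0.83. Each depended on 1 tumour: LUM was -0.66 without IgG control 2, SFRP2 -2.05 without IgG control 1 and COL3A1 -0.43 without anti-ENG 1. In either list 0 genes passed when adjusted over the list alone. Without both IgG control 1 and anti-ENG 1, the camera adjusted p was 0.119 for the collagen list and 0.144 for the fibroblast list, and the medians were -0.064 and -0.072. Without anti-ENG 1 alone the collagen median was -0.18 (camera adjusted p = 0.000797) and the fibroblast median -0.34 (0.049), and without IgG control 1 alone the fibroblast median was -0.46 (0.00728).

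**Figure D2:**
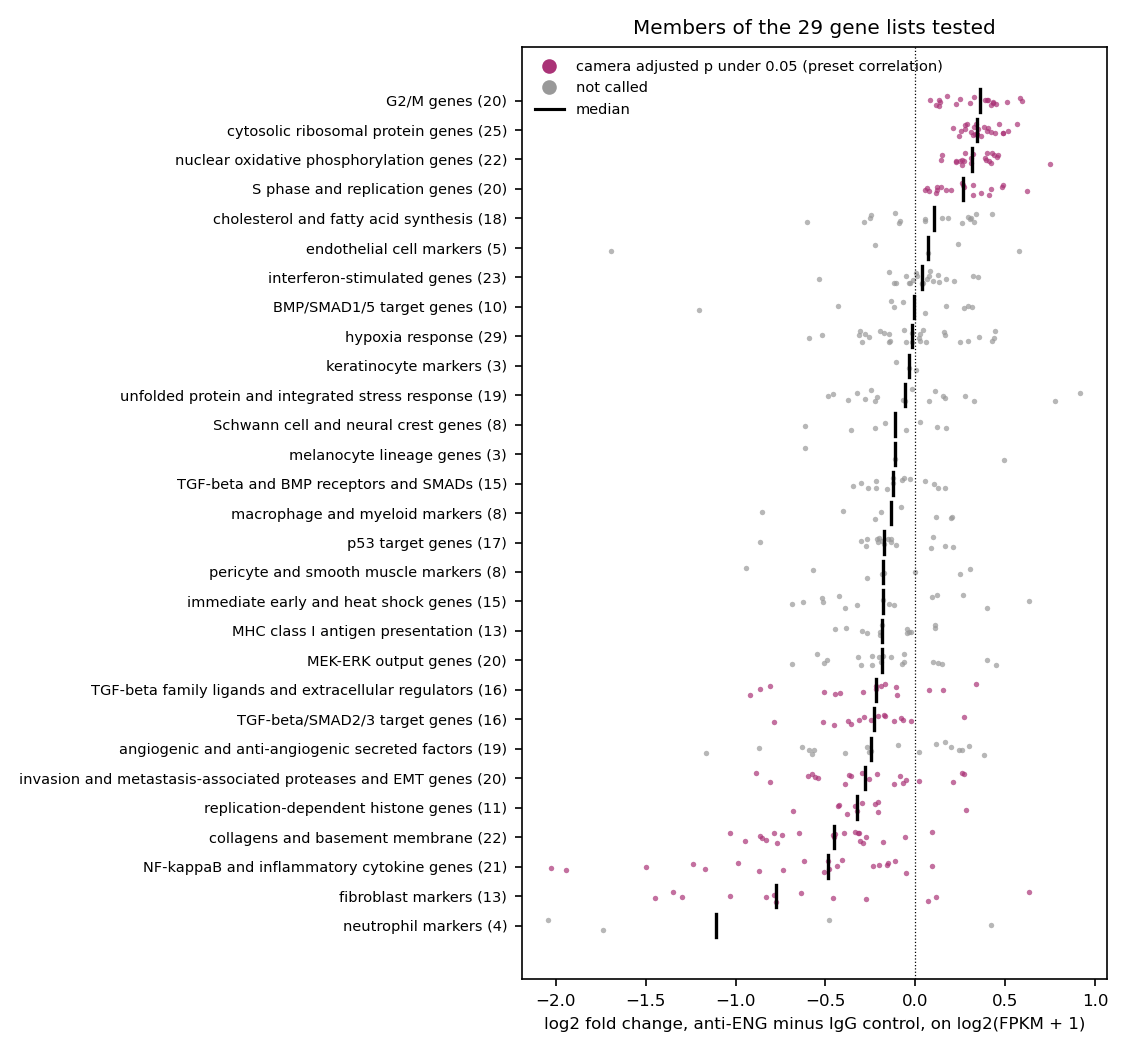
Log2 fold change, anti-ENG minus IgG control, of each tested member (points) of the 29 gene lists, with the number of members in parentheses, vertical lines at list medians, and colour for a camera adjusted p under 0.05 at the preset correlation. All 22 oxidative phosphorylation, 25 ribosomal, 20 S phase and 20 G2/M members lie above 0, and 21 of 22 collagen and basement membrane members lie below 0.

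Of the pathway in which endoglin acts, ligands and extracellular regulators of the TGF-beta family were lower in 13 of 16 members, with the groups apart in 1 (median log2 fold change -0.22, camera adjusted p = 0.0041, and adjusted p = 0.783 with an estimated correlation). TGFB1 had 121 ± 21.4 and 97.2 ± 1.37 FPKM (SD, n = 3 each). The latent TGF-beta binding protein genes LTBP1 and LTBP4 had log2 fold changes of -0.42 and -0.45, and BMP7 had -0.92. TGF-beta/SMAD2/3 target genes were lower in 15 of 16 members, with the groups apart in 0 (median -0.23, camera adjusted p = 0.0202, and adjusted p = 0.783 with an estimated correlation). FN1 had a log2 fold change of -0.45 and COL1A1 one of -0.79. Without anti-ENG 1 these values were -0.15 for FN1 and -0.32 for COL1A1. Without both IgG control 1 and anti-ENG 1 the median of the ligand list was -0.13 (camera adjusted p = 0.119). BMP/SMAD1/5 target genes went both ways, 5 higher and 5 lower (median -0.0070, camera adjusted p = 0.669), with HEY1 at -1.21. Their median was above 0 after quantile (0.024) and cyclic loess (0.0057) normalization. Receptors and SMADs had a median of -0.12 (camera adjusted p = 0.176), with BMPR2 at -0.30 and ACVR1 at -0.22. MEK-ERK output genes had a median of -0.19 (camera adjusted p = 0.175), with FOS at -0.69 and FOSL1 at 0.45. With tumours of one code number averaged the MEK-ERK list was called lower (median -0.26, camera adjusted p = 0.0102), as it was without IgG control 3 (0.00523) and without anti-ENG 2 (0.0251). Without IgG control 1 its median was 0.0036 (0.958). In these 5 lists 0 genes passed when adjusted over the list alone. The SMAD2/3 target call was lost without IgG control 1 (median -0.11, camera adjusted p = 0.547), without anti-ENG 1 (-0.15, 0.234), without anti-ENG 2 (-0.16, 0.0668) and with the length and GC correction (-0.20, 0.0802). The SMAD2/3 target median was 0.0027 without both IgG control 1 and anti-ENG 1 (camera adjusted p = 0.8315).

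Genes of invasion and of the epithelial-mesenchymal transition were lower in 16 of 20 members, with the groups apart in 1 (median log2 fold change -0.28, camera adjusted p = 0.0194, and adjusted p = 0.783 with an estimated correlation). ITGB3 had 12.6 ± 3.42 and 8.13 ± 0.514 FPKM (SD, n = 3 each), the membrane protease gene MMP14 had a log2 fold change of -0.89 and TWIST1 -0.26. The MMP14 value was -0.48 without IgG control 1. NF-kappaB and inflammatory cytokine genes were lower in 20 of 21 members, with the groups apart in 0 (median -0.49, camera adjusted p = 0.0202, and adjusted p = 0.852 with an estimated correlation). PTGS2, the inducible cyclooxygenase, had 12.7 ± 10.6 and 2.80 ± 3.73 FPKM (SD, n = 3 each), and IL1B had 219 ± 281 and 66.2 ± 95.5 (SD, n = 3 each). Adjusted over the list alone, 0 genes passed in either list. The invasion call was lost without IgG control 1, where the median was -0.040 (camera adjusted p = 0.914), and without anti-ENG 1 at a median of -0.21 (0.0647). The invasion median was 0.072 without both of these tumours (0.534). The NF-kappaB call was lost without IgG control 1 (0.922, with a median of 0.066), without anti-ENG 1 (0.819, median -0.13) and without anti-ENG 2 (0.186, median -0.27). It turned to a call of higher without both IgG control 1 and anti-ENG 1 (camera adjusted p = 0.0194, median 0.58).

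Vascular genes did not move together. RNA of mouse host vessels enters these values only where its reads align to the human genome, so these lists need not measure the vessels. Of 21 endothelial markers 5 were tested, with a median log2 fold change of 0.071, a mean of -0.21 and a downward camera direction (adjusted p = 0.669), so these signs differ. FLT1, the VEGF receptor 1 gene, had 6.70 ± 4.13 FPKM under IgG and 1.24 ± 0.590 under anti-ENG (SD, n = 3 each), a log2 fold change of -1.69. FLT1 was the 1 endothelial gene that passed when adjusted over the list alone, and its adjusted p over all genes was 0.529. ECSCR had a log2 fold change of 0.58. Secreted angiogenic and anti-angiogenic factors had a median of -0.25 (camera adjusted p = 0.243). VEGFA had 173 ± 24.9 and 115 ± 25.9 FPKM (SD, n = 3 each), THBS2, the angiogenesis inhibitor thrombospondin, had a log2 fold change of -1.17, VEGFB -0.26 and PDGFC 0.38. Pericyte and smooth muscle markers had a median of -0.18 (camera adjusted p = 0.312), with PDGFRB at -0.94 and NOTCH3 at -0.57. Hypoxia response genes had a median of -0.021 (camera adjusted p = 0.799), with the glycolytic genes ENO1 at 0.44 and PGK1 at 0.36 and the prolyl hydroxylase gene EGLN3 at 0.44. Adjusted over the list alone, 0 genes passed in the angiogenic, pericyte and hypoxia lists.

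Markers of other host and tumour cell states did not pass the threshold as lists. Host cells are mouse, so the same limit holds for their markers. Macrophage and myeloid markers had a median log2 fold change of -0.14 (8 tested, camera adjusted p = 0.614) and neutrophil markers one of -1.11 (4 tested, 0.638), with S100A9 at -2.04. The neutrophil median ran from -2.27 without anti-ENG 3, where the list was called lower (camera adjusted p = 0.0439), to -0.40 without IgG control 3. Keratinocyte markers had a median of -0.035 (3 tested, camera adjusted p = 0.805), Schwann cell and neural crest genes -0.11 (8 tested, 0.298) and melanocyte lineage genes -0.12 (3 tested, 0.568). NES, the progenitor filament nestin, had 56.1 ± 8.26 and 37.6 ± 12.5 FPKM (SD, n = 3 each), MC1R had a log2 fold change of -0.61 and MITF 0.49. Of natural killer and B cell markers 2 were tested and of adipocyte markers 1, too few for the list test. Of skeletal muscle and erythroid markers 0 reached the expression minimum. In the 5 tested lists of this group 0 genes passed when adjusted over the list alone.

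MHC class I genes had a median log2 fold change of -0.18 (camera adjusted p = 0.226), with HLA-F at -0.39 and TAPBP at -0.45. With tumours of one code number averaged this list was called lower (-0.27, 0.0171), and without IgG control 1 its median was 0.054. The list was called higher without both IgG control 1 and anti-ENG 1 (median 0.19, camera adjusted p = 0.026). Interferon-stimulated genes had a median of 0.039 (camera adjusted p = 0.791), which was below 0 after quantile (-0.067) and cyclic loess (-0.12) normalization and with samples rescaled to the same sum (-0.081). STAT2 had -0.54 and ISG15 0.35. P53 target genes had a median of -0.17 (camera adjusted p = 0.136), with RRM2B at 0.21 and SESN1 at -0.27. Genes of the unfolded protein and integrated stress response had a median of -0.060 and a mean of 0.0024 (camera adjusted p = 0.669), of differing sign. The amino acid synthesis genes PSAT1 and ASNS had log2 fold changes of 0.92 and 0.78, and the stress factor DDIT3 had -0.46. Cholesterol and fatty acid synthesis genes had a median of 0.10 (camera adjusted p = 0.262), which was -0.016 with samples rescaled to the same sum. In that list FDFT1, the squalene synthase gene, had 25.9 ± 1.86 and 35.0 ± 2.52 FPKM (SD, n = 3 each), and FDPS had a log2 fold change of 0.26. Immediate early and heat shock genes had a median of -0.18 (camera adjusted p = 0.372). The chaperone genes HSPA8 and HSP90AA1 had log2 fold changes of 0.63 and 0.40, and ZFP36 had -0.63. In these 6 lists 0 genes passed when adjusted over the list alone.

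**Figure D3:**
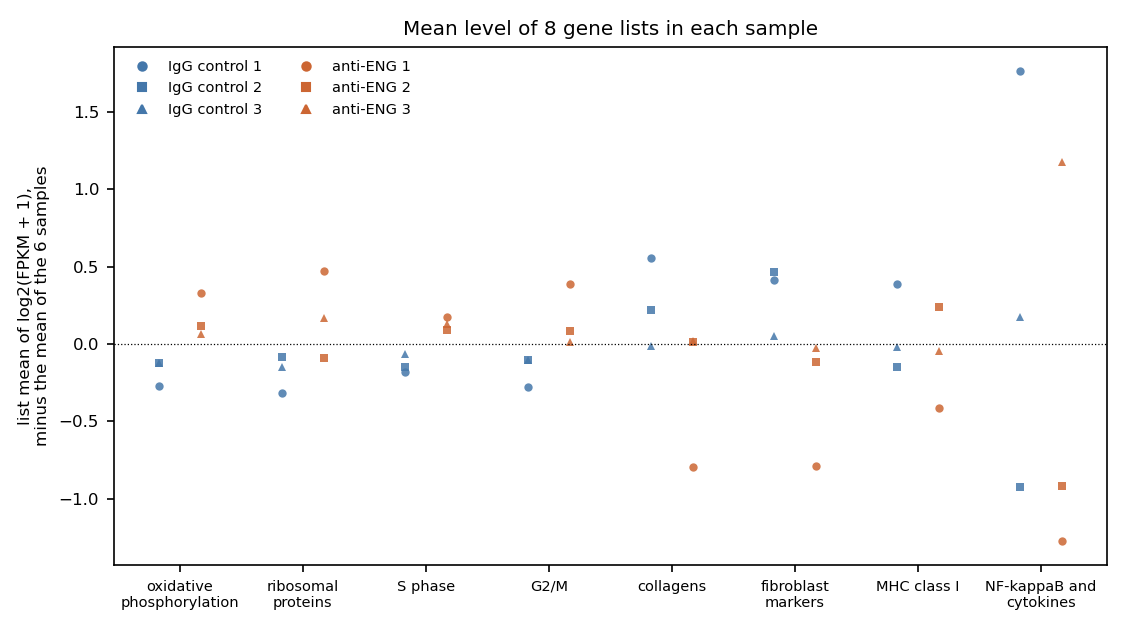
Mean log2(FPKM + 1) of 8 gene lists in each tumour, minus the mean of the 6 tumours, with 1 point per tumour. The tumours of the groups lie apart for the oxidative phosphorylation, S phase, G2/M and fibroblast list means, while for the ribosomal, collagen, MHC class I and NF-kappaB lists they overlap. In the fibroblast list 0 single members have the groups apart.

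**Figure D4:**
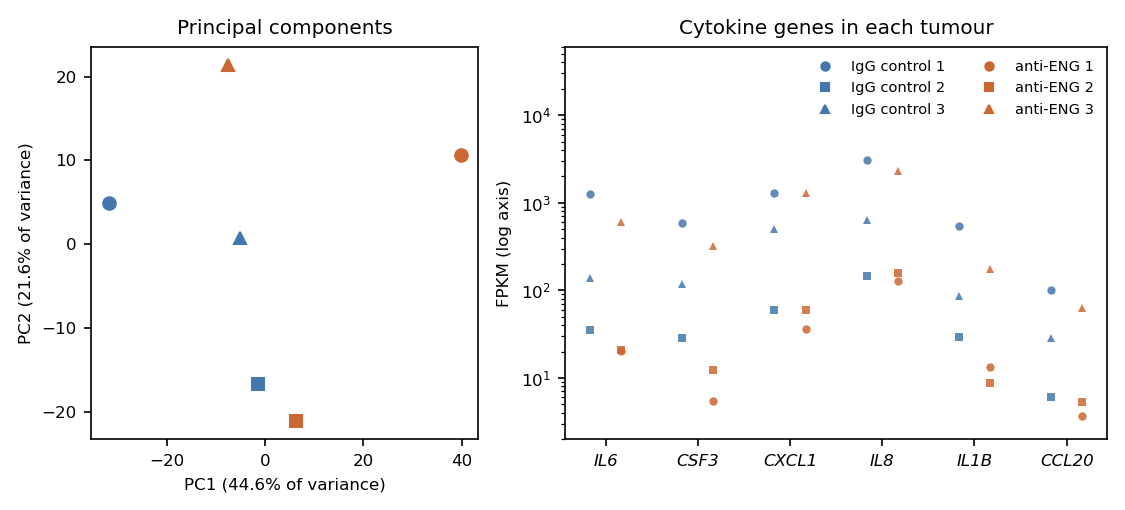
Left, the tumours on the first and second principal components (44.6 and 21.6% of variance). Right, FPKM of 6 cytokine genes on a log axis, 1 point per tumour, where IL6 runs from 20.2 to 1269 FPKM and both groups hold high and low tumours.

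In total camera called 11 of 29 lists at its preset correlation, 4 higher and 7 lower. With an estimated correlation 0 of these calls held, and fry called 0, with a smallest adjusted p of 0.0846 for the S phase list. For list means, exact permutation gave a two-sided p of 0.1, the smallest possible, for the oxidative phosphorylation, S phase, G2/M and fibroblast lists. Of single fibroblast members 0 had the groups apart. The calls of the histone, SMAD2/3 target, invasion and NF-kappaB lists were also lost with no filter on low values, with samples rescaled to the same sum and with array weights. With samples rescaled to the same sum their medians were -0.45, -0.35, -0.40 and -0.61, beside the -0.108 of all genes, and with no filter they were -0.26, -0.21, -0.21 and -0.49. With array weights they were -0.24, -0.12, -0.13 and 0.11.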

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

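Cyclic loess normalization, leaving out both IgG control 1 and anti-ENG 1, and the length and GC correction were added after seeing the data, as was the count of genes at an unadjusted p under 0.05. The counts of genes past the limma adjusted threshold were 0 higher and 0 lower in every setting run. The oxidative phosphorylation, S phase and G2/M lists were called by camera at its preset correlation in every setting run. With an estimated correlation 0 lists were called, and by fry 0. The number called was 7 with no filter on low values, 7 with samples rescaled to the same sum, 7 with array weights and 7 without both IgG control 1 and anti-ENG 1. It ran from 7 to 15 when 1 tumour was left out, with 7 without IgG control 1, 7 without anti-ENG 1 and 15 without IgG control 3. Genes at an unadjusted p under 0.05 numbered 735 without both IgG control 1 and anti-ENG 1. Among the 9922 genes with a mouse orthologue symbol they numbered 952 uncorrected and 662 with the length and GC correction. Among all 12586 genes with 1 tumour left out, such genes ran from 662 without IgG control 2 to 1566 without anti-ENG 2. They numbered 731 without IgG control 1 and 688 without anti-ENG 1.

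Replicate numbers did not pair the tumours: deviations from the group means correlated at -0.33, 0.19 and 0.037 for numbers 1, 2 and 3. With the replicate block, 0 genes were higher and 0 lower, 842 genes had an unadjusted p under 0.05 and 11 lists were called. With the code number as a random block 1653 genes had an unadjusted p under 0.05 and 11 lists were called. The fitted correlation within code numbers was -0.188. A negative value narrows the error of the group difference, so the larger count is no added support. Averaging tumours of one code number gave 877 such genes and 13 lists called, with the MEK-ERK and MHC class I lists added. The interferon list had a median of -0.068 there.

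Without both IgG control 1 and anti-ENG 1, ENG had a log2 fold change of 0.28, BAMBI 0.10, LAPTM5 0.35, TAPBP 0.027 and HLA-F 0.062, each reversed. List medians that reversed there were NF-kappaB 0.58 (camera adjusted p = 0.0194), MHC class I 0.19 (0.026), BMP/SMAD1/5 targets 0.27, macrophage 0.27, p53 0.14, stress response 0.11, hypoxia 0.096, invasion 0.072, immediate early 0.070, angiogenic 0.059, pericyte 0.029, SMAD2/3 targets 0.0027 and histones 0.00070. The interferon list was called higher there (median 0.28, camera adjusted p = 0.00389). With array weights the reversed medians were BMP/SMAD1/5 targets 0.14, NF-kappaB 0.11, macrophage 0.077, angiogenic 0.054, MHC class I 0.053, stress response 0.030 and hypoxia 0.025.

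The interferon median was -0.067 with quantile normalization, -0.12 with cyclic loess and -0.081 with samples rescaled to the same sum, where the cholesterol median was -0.016. The BMP/SMAD1/5 target median was 0.0087 with a pseudocount of 0.1, 0.10 at a minimum of 5 FPKM, 0.024 with quantile normalization, 0.030 with the code number block and 0.0057 with cyclic loess. The keratinocyte median was 0.0037 with a pseudocount of 5, the endothelial median -0.014 with no filter and the stress response median 0.043 with the length and GC correction. MHC class I genes were called lower with quantile normalization (camera adjusted p = 0.00177), cyclic loess (0.00301), code numbers averaged (0.0171), and without IgG control 2 (0.0225) or anti-ENG 2 (0.0108).

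With 1 tumour left out in turn, the log2 fold change of ENG ran from -0.44 to 0.0070. Of 77 list members followed singly, 39 moved by over 1.5 times on leaving out at least 1 tumour and 0 changed sign, against 0 and 0 of the 24 genes of smallest p. Both sets were picked by p in these same tumours, the 24 genes from all those tested, which favours this contrast. List medians ran from -1.2 to 0.066 for NF-kappaB, -0.52 to 0.074 for histones, -0.49 to 0.027 for pericyte, -0.36 to 0.054 for MHC class I, -0.32 to 0.0036 for MEK-ERK, -0.29 to 0.020 for angiogenic, -0.26 to 0.25 for endothelial, -0.23 to 0.14 for macrophage and -0.23 to 0.0026 for p53 lists. They ran from -0.20 to 0.18 for interferon, -0.18 to 0.22 for BMP/SMAD1/5 targets, -0.15 to 0.15 for hypoxia, -0.14 to 0.064 for stress response, -0.067 to 0.074 for keratinocyte and -0.020 to 0.21 for cholesterol lists. Without a change of sign, medians ran from -2.27 to -0.40 for neutrophil, -0.94 to -0.34 for fibroblast, -0.60 to -0.18 for collagen, -0.48 to -0.11 for SMAD2/3 target, -0.45 to -0.040 for invasion, -0.40 to -0.098 for immediate early, -0.30 to -0.22 for TGF-beta ligand, -0.19 to -0.046 for Schwann cell, -0.16 to -0.064 for melanocyte and -0.16 to -0.045 for receptor lists. They ran from 0.21 to 0.48 for ribosomal, 0.25 to 0.39 for oxidative phosphorylation, 0.23 to 0.39 for G2/M and 0.21 to 0.27 for S phase lists. Lists called by camera with 1 tumour left out and not with all 6 were MEK-ERK (adjusted p = 0.00523), BMP/SMAD1/5 targets (0.0432), receptors (0.0494) and immediate early genes (0.0494) lower without IgG control 3. Without IgG control 2 these were p53 targets (0.0225), MHC class I genes (0.0225) and angiogenic factors (0.0439), all lower. Without anti-ENG 2 they were MEK-ERK (0.0251), MHC class I (0.0108) and interferon genes (0.00679) lower and hypoxia (0.0472) and cholesterol genes (0.011) higher, and without anti-ENG 3 p53 targets (0.0111) and neutrophil markers (0.0439) lower. The cause of these changes was not tested. The total depth is unknown, so its share in the spread of low genes cannot be given.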

Other observations

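The per-list tests of an expression trend and of the tumours at the ends of the first principal component, the counts of splits for unadjusted p and for groups apart, and the 21 gene families with their left-out tumours were chosen only after the results were seen.

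Of the genes with the largest spread within groups, 4 inflammatory ones are given here, chosen for that spread. IL6 had 1269, 35.3 and 136.5 FPKM in IgG control 1, 2 and 3 and 20.2, 20.7 and 609.1 FPKM in anti-ENG 1, 2 and 3. IL8, the neutrophil chemokine, had 3088, 144.9 and 630.2 FPKM in the IgG tumours and 129, 156 and 2286 in the anti-ENG tumours. The granulocyte growth factor gene CSF3 had 586.9, 28.5 and 118.5 FPKM against 5.44, 12.2 and 320 FPKM. CXCL1 had 1288, 59.0 and 495.1 FPKM against 36.3, 59.5 and 1304 FPKM. They had within-group SDs of 2.69 (IL6), 2.26 (IL8), 2.61 (CSF3) and 2.54 (CXCL1) on the log2 scale.

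Gene families of mitochondria and protein turnover also had higher estimates in the anti-ENG tumours. The complex I family shares members with the oxidative phosphorylation list, such as NDUFS5. Genes of mitochondrial ribosomal proteins were higher in 74 of 78 members (median log2 fold change 0.26, camera adjusted p = 1.6e-14, and adjusted p = 0.22 with an estimated correlation). Complex I subunit genes were higher in 36 of 37 (median 0.33), proteasome subunit genes in 37 of 38 (0.25) and mitochondrial import genes in 20 of 22 (0.30), each with a camera adjusted p = 0.22 with an estimated correlation. HLA genes were lower in 16 of 17 (median -0.27, and adjusted p = 0.442 with an estimated correlation). The medians of these 5 families kept their sign under upper quartile, quantile, cyclic loess and same-sum scaling. After cyclic loess the 4 higher medians were smaller. They were 0.19 for mitochondrial ribosomal, 0.16 for complex I, 0.10 for proteasome and 0.21 for mitochondrial import genes, and the HLA median was -0.34. Without both IgG control 1 and anti-ENG 1 the medians were 0.16, 0.23, 0.21 and 0.15 for the 4 higher families in that order, each still called by camera at its preset correlation. The HLA median was -0.062 there (camera adjusted p = 0.935), -0.0026 without anti-ENG 1 (0.553) and -0.22 without IgG control 3 (0.0644), so that call was lost in each.

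The higher level of oxidative phosphorylation and ribosomal protein genes was weighed against a trend of fold change with expression level, the tumours at the ends of the first principal component, and length or GC bias. After cyclic loess normalization, the oxidative phosphorylation list kept 49.4% of its median (0.32 to 0.16, lower quartile above the median of all genes, camera adjusted p = 2.19e-05). The ribosomal list kept 18.9% (0.34 to 0.065, camera adjusted p = 0.0925), so a trend may account for its call, since all its members are among the most abundant genes; the median of all 81 ribosomal protein genes went from 0.36 to 0.10 (camera adjusted p at the preset correlation 4.7e-19 before and 0.000784 after, and adjusted p = 0.337 with an estimated correlation before loess). Without both IgG control 1 and anti-ENG 1 these lists kept 60.4% and 48.5% and were still called (1.35e-06 and 0.00308), so part of each median remained among the other tumours. Camera at this preset called as many lists as the real 11 in 6 of 10 splits of the tumours. These calls therefore cannot settle how far those tumours account for the pattern. The length and GC correction left at least 61.6% in each, and the test written first, that both lists keep at least 50%, was met by that correction and not by the other settings; an effect of the treatment stays open as a hypothesis.

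The lower collagen and fibroblast levels kept at least 108% of their medians after cyclic loess normalization. The trend ran upward, from a median of -0.076 in the lowest 10% of genes by expression to 0.16 in the top 10%. The top 10% held 11 of 22 collagen and 3 of 13 fibroblast members. Its direction argues against an expression trend for these abundant members, and made the loess result likely in advance. Without both IgG control 1 and anti-ENG 1 the collagen and fibroblast lists kept as little as 9.25%, and neither list was called, so the pattern may rest on those tumours. A lower share of host stroma cannot be told apart from it. The macrophage, endothelial and pericyte medians reached at most 0.071, and lay within the spread of their members of the value such a loss would need. These lists could not decide the question, since host cells are mouse and enter only where their reads align to the human genome. Of their markers 8 of 19 macrophage, 5 of 21 endothelial and 8 of 13 pericyte ones were tested. An effect of treatment on the cells that make collagen stays open and untested. Library kit and instrument could not be weighed for any of these patterns, since the labels do not assign them to samples.

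With 10 splits of the 6 tumours into 3 and 3, no share under 0.05 can be had. For genes past the adjusted threshold, 10 of 10 splits gave as many as the real 0 higher, and 10 of 10 as many as the real 0 lower, with a highest other of 0. A real count of 0 fixes this outcome, so these counts cannot bear on chance. Of the 10, 6 gave as many lists as the real 11, with a highest other of 20. For genes at an unadjusted p under 0.05, the real split gave 1154 and the highest other 1096, so 1 split, the real one, reached that count. For groups apart the real split gave 2183 and the highest other 1884, again 1 split. The highest other for both counts set IgG control 1, IgG control 3 and anti-ENG 3 against the rest.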
